A study of Arabidopsis thaliana with 72 samples.

How the data were processed

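Roots of 8-day-old Arabidopsis thaliana seedlings of 12 genotypes, grown with or without phosphate, were sequenced as 72 libraries, 3 per group in 24 groups. Per the labels' protocols, RNA was taken with a column kit, messenger RNA was purified with oligo(dT) beads, and plants stood on agar or on agarose plates, which the labels do not tell apart by library. The series calls the replicates biological, but the labels do not say that they came from separate cultures or plates, so the p-values may measure technical spread. The labels state neither strand nor read length.

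Gene values were taken as the authors deposited them, 1 table of RPKM (reads scaled by gene length and depth) with 33602 genes and 1 column per library. Per the submitters' processing notes, TopHat, edgeR and the TAIR10 build were used, with no versions, roles or order given. The columns were matched to the labels by name, 0 columns were left over and 0 pairs of columns were identical. In 5349 genes with 1 exon, low values were read as multiples of 1 step per library over gene length. The step was chosen to bring many low values close to a whole read. With it a median of 46.2% of low values lay within 0.05 of a whole read (38.5% to 53.8% over libraries). These steps gave an estimated depth of 11 to 40.4 M reads per library (median 22.9). At 22.9 M reads, 1 RPKM in a gene of 1 kilobase is about 22.9 reads. Column sums ran from 559809 to 742047 and were not equalised. Names, lengths, base content and neighbours of genes came from a reference annotation of TAIR10.1, to which 32835 IDs matched. No coordinates were used in the text, since that assembly is not the build of the deposited values.

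Log2(RPKM + 1) was modelled with limma (version 3.58.1 in R 4.3.3) in 1 fit of all 72 libraries with 24 group means and empirical Bayes moderation with trend and robust settings. Genes with at least 1 RPKM in at least 3 libraries were tested, 21206 in all. Adjusted p-values are by the Benjamini-Hochberg method over these genes, and a gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Comparisons were -Pi against +Pi in Col, each mutant against Col on either medium, steps from single to higher-order mutants under -Pi, the difference between each mutant's response and that of Col, and the non-additivity of 2 mutations. Gene lists were written from general knowledge of gene function (18 lists with 272 genes, of which 252 were tested) and tested with camera at a preset correlation of 0.01, adjusted over the 18 lists, and again with an estimated correlation. The share of the Col response kept was the median over the 1323 genes induced in Col of the mutant log2 change over the Col change, per -Pi library, compared with Col by exact permutation. The fits, comparisons, lists and alternatives were fixed before the data were examined, apart from the library classes.

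Library classes were defined after the data were seen. They rest on 9159 protein-coding genes outside the lists, with a mean log2 value above 2 and an absolute log2 Col response under 0.5. Changes in the mutants were not used to choose these genes, so a mutant effect can enter the slopes. The log2 deviation of each library was regressed on GC content, gene length and adenine content. Libraries were grouped by k-means on the 3 slopes with 50 starts (cluster version 2.1.8.1). The mean silhouette was 0.42, 0.56 and 0.47 for 2, 3 and 4 classes, and 3 were used. Fits with class as a term and fits of class 1 libraries alone were chosen after seeing the data.

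The other alternatives were a pseudocount of 0.1, no filter (29088 genes), rescaling of each library by its median ratio (factors 0.85 to 1.12), a fit of the compared groups alone, the replicate number as a block, each library left out in turn and, for the response kept, genes chosen on 2 Col replicates with the Col response taken from the remaining 1. Splits of the libraries were all 10 for 3 against 3 and 100 drawn at random for tests of 4 groups. Tables were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The fit was first tested on simulated values of 21206 genes with 200 changed, in 20 draws. For phl1 against Col under -Pi it recovered 97.3%, 98.7% and 99.8% of genes changed by a log2 of 1.5, 2 and 3, with at most 5 other genes called, and at most 1 with no change. For the difference in response between phl1 and Col it recovered 86.5%, 94.7% and 97.2%, with at most 9 others. The simulated values varied independently between libraries and held no library classes, so these rates do not cover differences between classes.

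Genes named in the text follow a rule fixed before the data were examined. It names the 5 PHR1 family genes, the 10 called genes with the largest log2 fold change in either direction for the Col response and for phr1, phr1phl1 and the quadruple mutant against Col under -Pi, the 3 in either direction for every other comparison, and the 4 members of each list with the largest absolute log2 fold change. Genes ranked by fold change also needed at least 5 RPKM in the higher group and no overlap between the groups. For tests of 4 groups, to which an overlap of libraries does not apply, the minimum was asked of the highest group. Not every gene that the rule allows is named. Markers of the shoot were named from a list of 13 written before the test that used it.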

Results

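Roots of 8-day-old Arabidopsis thaliana seedlings were profiled by RNA sequencing in 72 libraries. They covered the wild type Col-0 (Col) and 11 mutants in PHR1 and its relatives PHL1, PHL2, PHL3 and PHL4, a family of transcription factors that bind promoters of phosphate starvation genes. Each of the 12 genotypes was grown with phosphate (+Pi) and without it (-Pi), which gives 24 groups of 3 libraries. The mutants were phr1, phl1, phl2, phl3 and phl4, the double mutants phr1phl1, phr1phl2, phr1phl3 and phr1phl4, the triple mutant phr1phl1phl2 and the quadruple mutant phr1phl1phl2phl3. Depth, estimated from the steps between low values, ran from 11 to 40.4 M reads per library (median 22.9). Of 33602 genes in the table, 21206 were tested. A gene was called at an adjusted p under 0.05 and an absolute log2 fold change of at least 1. Levels are mean RPKM ± SD and log2 fold changes are ± SE, with n = 3 libraries per group throughout. All log2 fold changes and adjusted p-values come from limma, and those of gene lists from camera. Where 1 count is given for a list, the count adjusted over the list alone was the same. No library of either group overlapped the other group for the genes named by rank. Whether the libraries keep strand was not stated, so values of PHR1, CHS, OCT1 and CYP71A13, which overlap other genes, are uncertain. The same holds for near-identical pairs such as CYP71A12 and CYP71A13, PHT1;2 and PHT1;3, and the Rubisco subunit genes.

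The family genes were read first, as a check of the labels. PHR1 read 1.62 to 5.86 RPKM in the libraries of the 7 genotypes carrying phr1 and 15.8 to 27.7 in all others. PHL1 read 1.6 to 4.66 in libraries with phl1 in their label against 5.7 to 10.4 elsewhere. Against Col under -Pi its log2 fold change was -0.78 in phr1phl1 and -0.64 in the triple mutant, too small for a call. The adjusted p-values were 4.97e-07 and 1.96e-05. PHL2 read 0.67 to 4.38 with phl2 in the label against 12.2 to 37.2. PHL4 read 2.73 to 4.37 in phl4 and 3.84 to 5.02 in phr1phl4 against 3.21 to 18.7 elsewhere, with Col +Pi replicate 1 at 4.88, phl1 -Pi replicate 3 at 4.19 and all phl2 and phl3 libraries under -Pi (3.44 ± 0.217 and 3.59 ± 0.269) within these ranges. Against Col it was called lower in phl4 under -Pi only (log2 -1.10 ± 0.21, -0.83 and not called with the class term), and not in phl4 under +Pi (-0.72) or in phr1phl4 (-0.67 under -Pi, -0.43 under +Pi), though it was lower than in phr1 there under -Pi (-1.11 ± 0.21, -0.85 and not called with the class term). Loss of PHL4 is thus not shown by its transcript, and results for phl4 and phr1phl4 are given by label. PHL3 went against its label. It read 1.93 to 3.87 in phr1phl3 but 6.31 to 16.3 in the libraries labelled phl3 and 5.45 to 16.4 in those labelled quadruple, against 3.99 to 15.6 in the 54 libraries with no phl3 in their label. Results for the libraries labelled phl3 and quadruple are therefore given by label, without a claim that PHL3 was lost in them. In phr1phl3 PHL3 was called lower than in Col under +Pi (log2 -1.65 ± 0.26, -1.42 with the class term). Under -Pi it was not called there (-0.53 ± 0.26, adjusted p = 0.0801), though it was with the class term (-1.22).

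**Figure D1:**
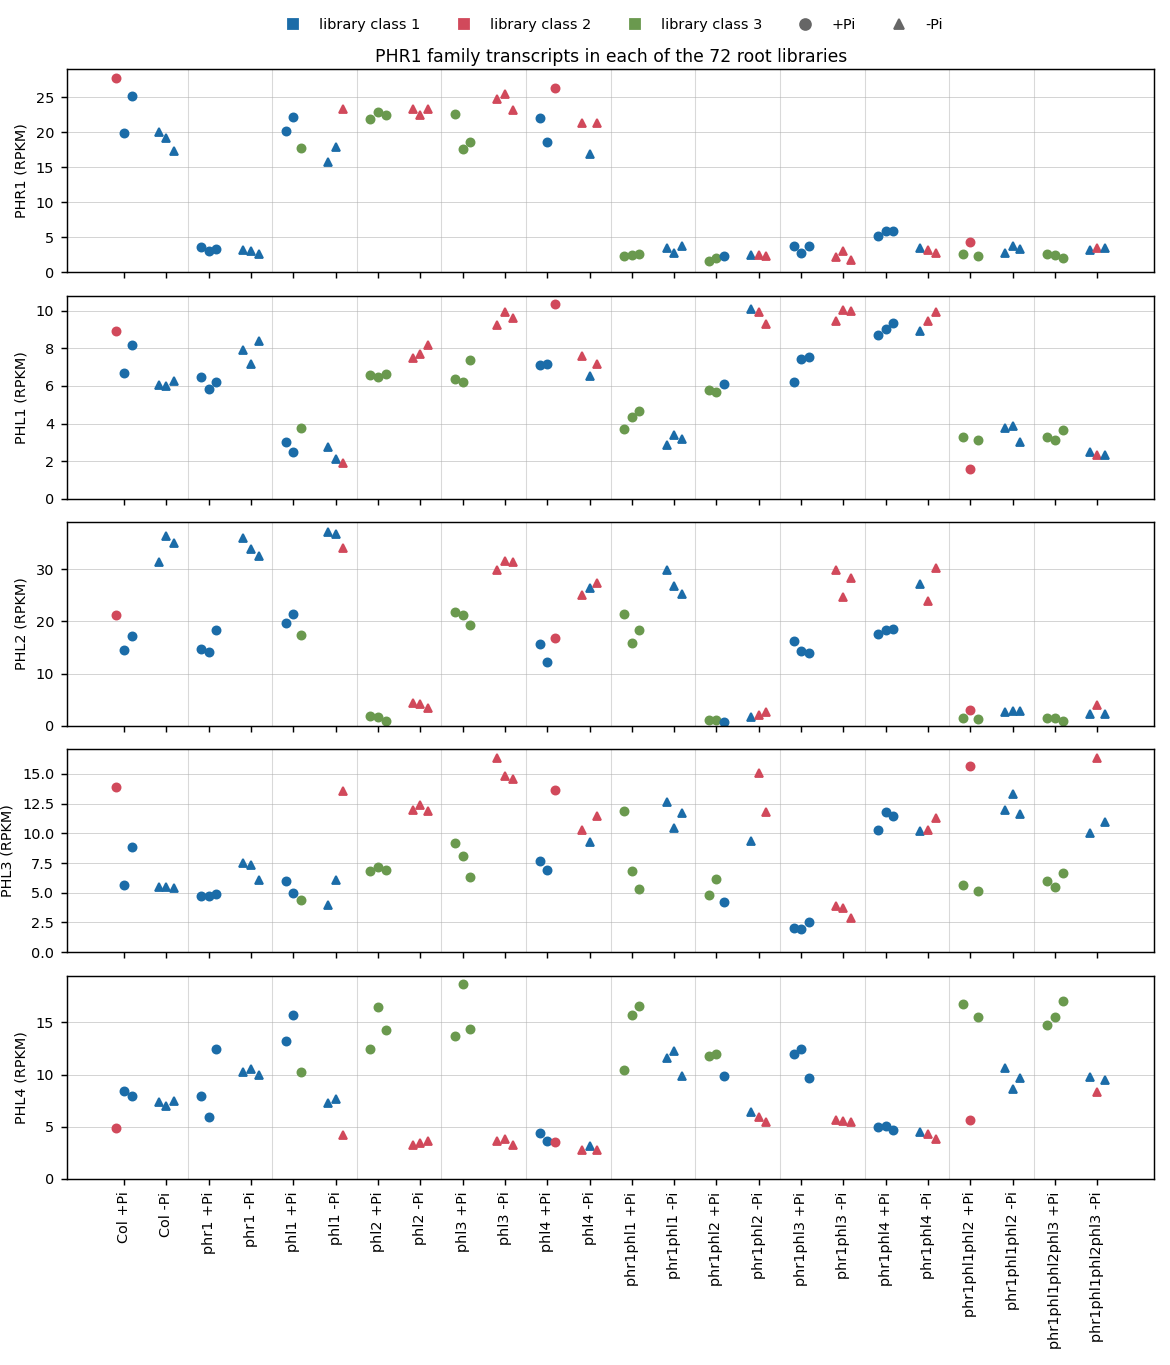
RPKM of the 5 PHR1 family genes in every library, by group. PHL3 reads 6.31 to 16.3 in the libraries labelled phl3, against 1.93 to 3.87 in phr1phl3.

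Libraries also fell into 3 classes that the groups did not explain, by how their values depended on gene length, GC content and adenine content. Class 1 held 35 libraries of both media, class 2 held 20 libraries, 17 of them -Pi, and class 3 held 17, all +Pi. Mean slopes on gene length were 0.015 ± 0.081, -0.225 ± 0.055 and 0.234 ± 0.058 (SD over libraries), and chloroplast genes took a median of 1.06%, 0.32% and 1.09% of the values. Under -Pi all 3 libraries of Col, phr1, phr1phl1 and the triple mutant were class 1, all 3 of phl2, phl3 and phr1phl3 were class 2, and phl1, phl4, phr1phl2, phr1phl4 and the quadruple mutant were mixed. Under +Pi, Col had 2 libraries of class 1 and 1 of class 2 (replicate 1), and all libraries of phl2, phl3, phr1phl1 and the quadruple mutant were class 3. Counts from a fit with class as an added term are given for every comparison whose count they move by over 1.5 times. For single genes a class term value is given only in some of these comparisons. Counts and adjusted p-values of gene lists come from the fit without class. Values with the class term rest on the 10 groups that hold more than 1 class. Class 3 shares a group with another class only in phl1, phr1phl2 and the triple mutant under +Pi. In each of these groups 1 library stands against 2. Class term values for groups wholly of class 3 therefore rest on few libraries.

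**Figure D2:**
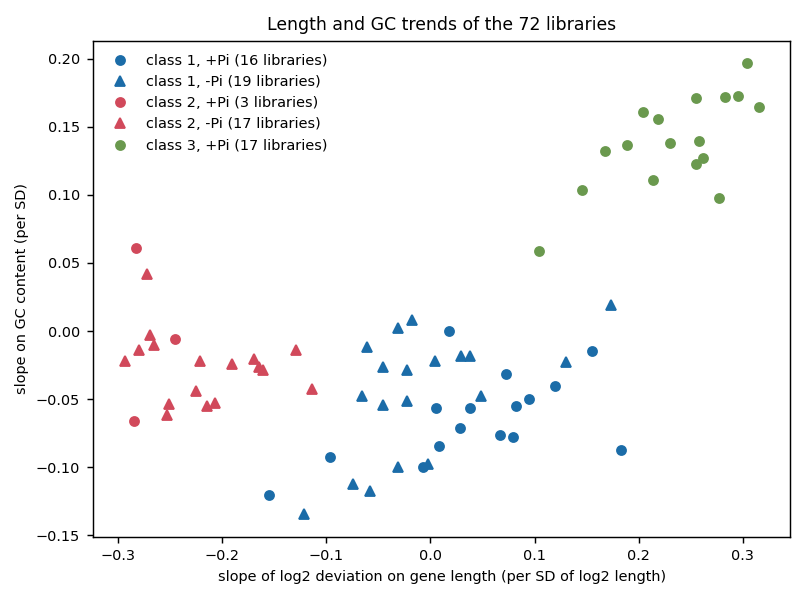
Slope of each library's log2 deviation on gene length against its slope on GC content, 1 point per library, coloured by class. The mean length slopes of the 3 classes are 0.015, -0.225 and 0.234.

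The response of Col roots to -Pi answers what phosphate starvation did in the wild type. Phosphate starvation genes rose together. IPS1, a non-coding RNA that sequesters microRNA399, rose by a log2 of 9.0 ± 0.31 (RPKM 2060 ± 303 against 3.45 ± 2.39, adjusted p = 5.79e-31). SPX3, a phosphate sensor protein of the SPX family, rose by 8.44 ± 0.20 (650 ± 12.3 against 0.925 ± 0.524). The precursor of microRNA399 MIR399D read 91.1 ± 36.6 under -Pi and was listed at 0 in the 3 +Pi libraries. 9 of 13 phosphate signalling genes were higher and 1 lower (median log2 3.48, adjusted p = 1.76e-08). 12 of 17 phosphate transport genes were higher and 1 lower (median log2 2.68, adjusted p = 2.96e-16), among them PHT1;2 at 5.92 ± 0.13 and PHT1;4 at 4.42 ± 0.10. 13 of 19 phosphatase and ribonuclease genes were higher (adjusted p = 1.72e-21), among them PECP1 at 7.82 ± 0.21, PS2 at 6.56 ± 0.21 and RNS1 at 4.78 ± 0.19. Of the lipid remodelling genes, which replace phospholipids with lipids free of phosphorus, 12 of 15 were higher (adjusted p = 4.58e-22), with the galactolipid synthase MGD3 at 5.99 ± 0.12 and the phospholipase NPC4 at 5.04 ± 0.17. 9 of 14 sulfate genes were higher (adjusted p = 8.52e-10), led by the transporters SULTR1;3 (5.23 ± 0.11) and SULTR2;1 (3.12 ± 0.18). 13 of 16 jasmonate genes were higher (adjusted p = 1.45e-12), with JAZ10 at 4.26 ± 0.18 and AOC1 at 4.13 ± 0.14. The jasmonate-responsive aminotransferase TAT3 rose by 6.53 ± 0.12.

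Other groups fell in Col under -Pi. 2 of 22 iron uptake genes were higher and 12 lower (median log2 -1.21, adjusted p = 4.34e-10). The root iron transporter IRT1 went from 341 ± 164 to 0.105 ± 0.132 RPKM (log2 -8.17 ± 0.21), the ferric reductase FRO2 fell (log2 -4.25 ± 0.15), and CYP82C4, which makes the iron-mobilising coumarin sideretin, went from 32.9 ± 1.58 to being listed at 0. 25 of 27 photosynthesis genes were lower (median log2 -3.33, adjusted p = 1.04e-21), with the Rubisco subunit RBCS1A at -5.44 ± 0.41 and PSBO2 at -4.86 ± 0.21. 6 of 7 flavonoid genes were lower (adjusted p = 4.17e-11), with CHI at -3.79 ± 0.26 and FLS1 at -3.47 ± 0.17. UMAMIT17, of an amino acid transporter family (-5.82 ± 0.16), the anion channel SLAH1 (-5.26 ± 0.17) and the aquaporin RD28 (-4.88 ± 0.18) also fell. 3 of 14 immune response genes were higher and 1 lower (adjusted p = 0.000472). 4 of 12 nitrate genes were higher and 2 lower (adjusted p = 0.122) with NRT1.8 at 2.87 ± 0.17 and NRT1.5 at -2.00 ± 0.10, 3 of 16 root hair genes higher (adjusted p = 0.00404) with RHD6 at 1.98 ± 0.17. 2 of 6 iron storage genes were lower (adjusted p = 0.122). 1 of 11 low oxygen genes was higher (adjusted p = 0.0735). 1 of 12 endodermal barrier genes was higher (adjusted p = 0.756). 1 of 8 root tip phosphate and aluminium genes was higher (adjusted p = 0.681). 1 of 18 dividing cell and root tip genes was higher (adjusted p = 0.132). The PHR1 family itself had a median log2 of -0.32 (adjusted p = 0.756). In all, 1323 higher and 1738 lower genes were called in Col. They were 1220 higher and 1378 lower with the class term, and 2419 genes were called in both fits.

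**Figure D3:**
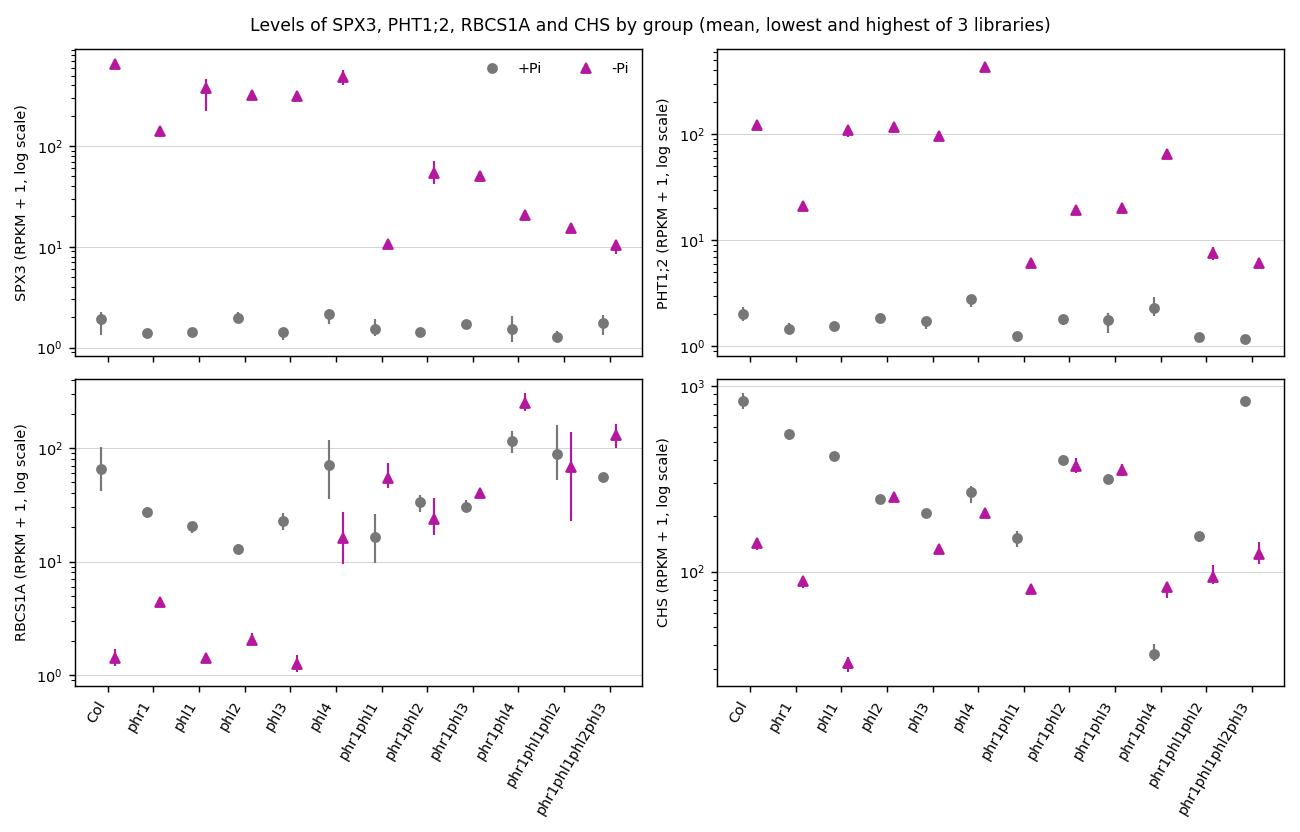
RPKM of genes named in the text, by group and on a log axis, with the group means. SPX3 lies at 650 RPKM in Col under -Pi.

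Loss of PHR1 alone lowered phosphate starvation genes under -Pi. The median log2 response to -Pi within phr1 was 1.77 for phosphate signalling genes and 0.79 for phosphate transport genes. It was 1.06 for phosphatase and ribonuclease genes and 2.01 for lipid remodelling genes. In Col these medians were 3.48, 2.68, 2.44 and 2.65. The response within phr1 was not tested by itself. SPX3 fell to 139 ± 16 from 650 ± 12.3 (log2 -2.23 ± 0.20, adjusted p = 5.12e-13), and IPS1 fell (log2 -1.28 ± 0.31, adjusted p = 0.0761 with a pseudocount of 0.1). MIR399D fell to 0.96 ± 0.683 from 91.1 ± 36.6, and so did the transporters PHT1;7 and PHT1;2 (log2 -3.27 ± 0.07 and -2.55 ± 0.13). 6 of 13 phosphate signalling genes were lower, or 7 lower adjusted over the list alone (adjusted p = 6.24e-09). 7 of 17 phosphate transport genes were lower (adjusted p = 7.19e-27). 9 of 19 phosphatase and ribonuclease genes were lower (adjusted p = 9.93e-37). 8 of 15 lipid remodelling genes were lower (adjusted p = 1.7e-28), with the sulfolipid synthase SQD2 at -2.18 ± 0.12. 8 of 14 immune response genes were higher (median log2 1.26, adjusted p = 2.69e-21). CYP71A12 and CYP71A13, which act in the synthesis of camalexin and related indolic defence compounds, rose by 5.68 ± 0.11 (286 ± 8.61 against 4.58 ± 0.369) and 5.01 ± 0.10. CYP82C2 of the same metabolism rose by 5.10 ± 0.07 (37.3 ± 1.53 against 0.119 ± 0.0785) and the immune regulator WRKY70 by 3.08 ± 0.22. 8 of 27 photosynthesis genes were higher (adjusted p = 0.00151, and adjusted p = 0.426 with an estimated correlation). 3 of 14 sulfate genes were lower (adjusted p = 3.74e-07). Of the genes of highest rank, GSTF3 and GLIP1 rose by 4.27 and 3.95, and the orphan gene QQS fell (log2 -4.01). In all, 492 higher and 166 lower genes were called, from 6 libraries of class 1, and 1079 in total with a pseudocount of 0.1.

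The single phl1 mutant differed little from Col under -Pi. 3 of 7 flavonoid genes were lower (median log2 -1.0, adjusted p = 1.6e-19), led by chalcone synthase CHS at -2.16 ± 0.10 (31.1 ± 3 against 142 ± 11.4) and FLS1 at -1.39 ± 0.17. 2 of 13 phosphate signalling genes were lower (adjusted p = 0.000321), the precursors MIR399D (-1.75 ± 0.31) and MIR399B (-1.04 ± 0.17). MIR399B was at -0.98 without Col -Pi replicate 2 and at -1 without phl1 -Pi replicate 2. In a fit of phl1 and Col alone the calls of FLS1, MIR399D, MIR399B and JMJD5 ended (adjusted p = 0.181, 0.709, 0.154 and 0.11), and those of MIR399D and MIR399B also with a pseudocount of 0.1 (adjusted p = 0.083 and 0.095). QQS fell to 0.886 ± 0.32 from 111 ± 17.9, and JMJD5, a jumonji protein of the circadian clock, rose by 1.59 ± 0.14. There were 17 higher and 36 lower genes called, and the total was 80 without phl1 -Pi replicate 1, 4 in a fit of phl1 and Col alone and 96 with a pseudocount of 0.1.

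In phl2 under -Pi, 4 of 7 flavonoid genes were higher than in Col (median log2 1.39, adjusted p = 3.09e-06). CHI rose (log2 2.60 ± 0.26, 1.88 with the class term) and so did FLS1 (log2 2.16 ± 0.17, 1.93 with the class term). MIR399D was lower (log2 -1.44 ± 0.31, -1.36 with the class term). The 3 phl2 libraries are all class 2 and the 3 Col libraries all class 1. The main count of 2269 higher and 941 lower genes came to 136 higher and 86 lower with the class term, with 164 genes called in both. The libraries labelled phl3 were likewise all class 2, and 2173 higher and 761 lower genes became 71 higher and 47 lower with the class term (68 in both). The defensin gene PDF2.1 was higher there (3.37 ± 0.50, 1.85 with the class term) and in phl2 (3.82 ± 0.50, 2.30 with the class term), and QQS was lower in both (-5.71 ± 0.41, -5.11 with the class term, and -5.30 ± 0.41, -4.70 with the class term). No direction is drawn for loss of PHL3, since PHL3 read 15.2 ± 0.946 in these libraries and 5.45 in Col.

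In phl4 under -Pi, some phosphate transport and phosphatase genes stood above Col. Phosphate signalling genes had a median log2 of 0.12 (adjusted p = 0.584, 1 of 13 lower) and lipid remodelling genes one of 0.17 (adjusted p = 0.265, 0 called). The transporters PHT1;3 and PHT1;2 rose by 2.11 ± 0.07 and 1.81 ± 0.13, among 4 of 17 phosphate transport genes higher (adjusted p = 3.21e-05), and PECP1 rose to 712 ± 141 from 284 ± 23.8, among 5 of 19 phosphatase and ribonuclease genes higher (adjusted p = 1.26e-09). 6 of 16 root hair genes were higher (adjusted p = 8.61e-08), with COW1, a lipid transfer protein of root hair growth, at 1.97 ± 0.09 (41.2 ± 1.21 against 9.8 ± 0.156), the root hair regulator RSL2 at 1.90 ± 0.19 and the cell wall protein PRP3 at 1.70 ± 0.14. 1 of 16 jasmonate genes was higher and 6 lower (adjusted p = 4.64e-06), with the repressors JAZ8 and JAZ7 at -1.94 ± 0.19 and -1.81 ± 0.35. 17 of 27 photosynthesis genes were higher, or 18 higher adjusted over the list alone (adjusted p = 1.93e-12, and adjusted p = 0.0535 with an estimated correlation). 3 of 12 nitrate genes were higher and 1 lower (adjusted p = 0.0103), with the nitrate uptake partners NRT3.1 and NRT2.1 at 2.12 ± 0.29 and 1.61 ± 0.12. The glycine-rich protein gene GRP-3 rose by 5.21 ± 0.41 and the marneral synthase gene MRN1 fell (-3.26 ± 0.15). The count of 1138 higher and 698 lower genes came to 444 higher and 285 lower with the class term (615 in both), and the total was 3085 without phl4 -Pi replicate 2 and 1170 without phl4 -Pi replicate 3. It was 2776 with a pseudocount of 0.1.

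The phr1phl1 double mutant asks what PHL1 adds to PHR1, and its 6 libraries with Col under -Pi were all class 1. IPS1 and SPX3 fell further than in phr1. IPS1 read 32.6 ± 10.7 against 2060 ± 303 (log2 -5.97 ± 0.31, adjusted p = 6.03e-23), SPX3 9.76 ± 0.725 against 650 ± 12.3 (-5.92 ± 0.20) and PECP1 fell (log2 -5.71 ± 0.21). MIR399D was listed at 0 in all 3 phr1phl1 libraries. 2 of 13 phosphate signalling genes were higher and 8 lower (adjusted p = 3.86e-06). 10 of 17 phosphate transport genes were lower (adjusted p = 1.06e-20). 11 of 19 phosphatase and ribonuclease genes were lower (adjusted p = 5.32e-20). 11 of 15 lipid remodelling genes were lower (adjusted p = 1.73e-20), with NPC4 at -4.84 ± 0.17 and MGD3 at -4.59 ± 0.12. 7 of 14 sulfate genes were lower (adjusted p = 3.01e-11), with SULTR1;3 at -5.01 ± 0.11 and SULTR2;1 at -4.39 ± 0.18. Of the endodermal barrier genes, which build the suberin and diffusion barriers of the root, 5 of 12 were lower (adjusted p = 1.03e-07), with KCS2 at -1.46 ± 0.10 and FAR4 at -1.38 ± 0.20. 21 of 27 photosynthesis genes were higher (median log2 1.82, adjusted p = 1.08e-10, and adjusted p = 0.0651 with an estimated correlation), with RBCS1A at 53.5 ± 17.2 against 0.422 ± 0.25. The sucrose exporter SWEET12 rose by 5.65 ± 0.16 (98.3 ± 13.2 against 0.977 ± 0.191), the scaffold protein gene BT2 by 5.58 ± 0.13 and the metallothionein MT2A by 4.86 ± 0.44. The amino acid exporter UMAMIT14 fell (-5.42 ± 0.26), as did the organic cation transporter OCT1 (-6.94 ± 0.14) and the sucrose synthase SUS4 (-2.71 ± 0.10). In all, 1484 higher and 956 lower genes were called, and the share of calls that were higher was 60.8% (51.1% after rescaling).

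In phr1phl2 and in phr1phl3, phosphate starvation genes fell below Col under -Pi and flavonoid genes stood above it. PHL3 read 3.48 ± 0.513 in phr1phl3 against 5.45 ± 0.0375 in Col, a difference called with the class term only. The log2 fold change of SPX3 was -3.63 ± 0.20, -3.35 with the class term, in phr1phl2 and -3.68 ± 0.20, -3.26 with the class term, in phr1phl3. That of NPC4 was -2.88 ± 0.17, -2.57 with the class term, and -3.15 ± 0.17, -2.69 with the class term. 5 of 13 phosphate signalling genes were lower in phr1phl2 (adjusted p = 1.74e-05) and 6 of 13 lower in phr1phl3 (adjusted p = 0.000148). 9 of 15 lipid remodelling genes were lower (adjusted p = 4.9e-16) and 9 of 15 lower (adjusted p = 1.29e-14). 5 of 7 flavonoid genes were higher (adjusted p = 1.78e-07) and 5 of 7 higher (adjusted p = 7.43e-07), with FLS1 at 3.21 ± 0.17, 3.06 with the class term, and at 2.95 ± 0.17, 2.72 with the class term. 6 of 14 immune response genes were higher (adjusted p = 4.75e-09) and 7 of 14 higher (adjusted p = 4.8e-07), with CYP71A12 at 4.98 ± 0.11, 4.86 with the class term, and at 5.37 ± 0.11, 5.20 with the class term. 17 of 27 photosynthesis genes were higher (adjusted p = 1.74e-05, and adjusted p = 0.218 with an estimated correlation) and 18 of 27 higher (adjusted p = 7.43e-07, and adjusted p = 0.158 with an estimated correlation). Of 3 libraries, 2 were class 2 in phr1phl2 and 3 in phr1phl3. Counts of 2218 higher and 831 lower and of 3215 higher and 1096 lower genes came to 894 higher and 460 lower and 1010 higher and 393 lower with the class term (1184 and 1172 in both fits). The share of calls that were higher was 72.7% (59.9% after rescaling) in phr1phl2 and 74.6% (66.7% after rescaling) in phr1phl3.

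In phr1phl4 under -Pi, 25 of 27 photosynthesis genes were higher than in Col (median log2 4.68, adjusted p = 6.24e-25). RBCS1A read 248 ± 49.5 against 0.422 ± 0.25 (log2 7.45 ± 0.41, 6.93 with the class term) and the photosystem subunit gene PSAD1 rose (log2 6.03 ± 0.36, 5.47 with the class term). Phosphate starvation genes fell. SPX3 read 19.7 ± 2.05 against 650 ± 12.3 (-4.98 ± 0.20, -4.70 with the class term) and IPS1 fell (log2 -4.03 ± 0.31, -3.54 with the class term). 1 of 13 phosphate signalling genes was higher and 8 lower (adjusted p = 0.000292). 2 of 17 phosphate transport genes were higher and 6 lower (adjusted p = 3.81e-07). 10 of 19 phosphatase and ribonuclease genes were lower (adjusted p = 3.55e-11). 10 of 15 lipid remodelling genes were lower (adjusted p = 6.58e-14). 9 of 16 jasmonate genes were lower (adjusted p = 7.31e-09). 8 of 14 sulfate genes were lower (adjusted p = 4.56e-05). 5 of 12 endodermal barrier genes were lower (adjusted p = 9.97e-06). Of the 3 libraries 2 were class 2, and 2729 higher and 1284 lower genes became 1768 higher and 901 lower with the class term (2365 in both).

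Phosphate starvation genes were also low in the triple and the quadruple mutant under -Pi. SPX3 read 14.4 ± 0.715 and 9.45 ± 1.8, against 650 ± 12.3 in Col, and IPS1 had log2 fold changes of -4.76 ± 0.31 and -5.24 ± 0.31. In the triple mutant 2 of 13 phosphate signalling genes were higher and 7 lower (adjusted p = 4.1e-05). 10 of 17 phosphate transport genes were lower (adjusted p = 4.28e-21). 12 of 19 phosphatase and ribonuclease genes were lower (adjusted p = 1.13e-18). 10 of 15 lipid remodelling genes were lower (adjusted p = 2.35e-19). In the libraries labelled quadruple the same lists gave 2 of 13 higher and 8 lower (adjusted p = 1.74e-05), 11 of 17 lower (adjusted p = 1.94e-17), 12 of 19 lower (adjusted p = 4.05e-17) and 11 of 15 lower (adjusted p = 1.97e-17). 7 of 14 sulfate genes were lower (adjusted p = 9.49e-13) and 9 of 14 lower (adjusted p = 8.6e-12). 6 of 12 endodermal barrier genes were lower (adjusted p = 4.39e-10) and 7 of 12 lower (adjusted p = 1.26e-08), with KCS2 at -1.57 ± 0.10 and -1.49 ± 0.10. 23 of 27 photosynthesis genes were higher (adjusted p = 9.02e-11, and adjusted p = 0.0605 with an estimated correlation) and 24 of 27 higher (adjusted p = 1.03e-13), with RBCS1A at 5.19 ± 0.41 and 6.51 ± 0.41 (130 ± 31.4 RPKM in the quadruple mutant). NAS2, a nicotianamine synthase of iron transport, fell in both (log2 -2.86 ± 0.16 and -2.96 ± 0.16). In the quadruple mutant MT2A rose by 5.96 ± 0.44, BT2 by 5.46 ± 0.13 and the glycine-rich protein gene GRP3S by 6.33 ± 0.36, and OCT1 (-7.04 ± 0.14), UMAMIT14 (-5.29 ± 0.26) and SULTR1;3 (-5.02 ± 0.11) fell. There were 1656 higher and 977 lower and 2425 higher and 1199 lower genes called, with 62.9% (52.9% after rescaling) and 66.9% (58.8% after rescaling) of calls higher.

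Steps between mutants under -Pi asked what each further mutation added. Adding phl1 to phr1 lowered IPS1 to 32.6 ± 10.7 from 852 ± 140 (log2 -4.70 ± 0.31), lowered SPX3 (log2 -3.69 ± 0.20) and raised PHO2, the ubiquitin-conjugating enzyme that microRNA399 targets, by 2.29 ± 0.28. 8 of 17 phosphate transport genes were lower (adjusted p = 4.02e-11). 3 of 15 lipid remodelling genes were lower (adjusted p = 2.54e-08). 2 of 13 phosphate signalling genes were higher and 5 lower (adjusted p = 0.0168, and adjusted p = 0.0806 with an estimated correlation). 2 of 19 phosphatase and ribonuclease genes were higher and 4 lower (median log2 -0.20, adjusted p = 0.00208, and adjusted p = 0.0746 with an estimated correlation). 5 of 14 sulfate genes were lower (adjusted p = 1.43e-07). Of the immune response genes, which were high in phr1, 9 of 14 were lower (adjusted p = 4.3e-14), with CYP71A12 at 13.2 ± 0.709 against 286 ± 8.61. Adding phl4 to phr1 left 25 of 27 photosynthesis genes higher (adjusted p = 2.66e-31). 4 of 16 root hair genes were higher (adjusted p = 0.0375), with COW1 at 1.67 ± 0.09. 6 of 14 immune response genes were lower (adjusted p = 2.92e-08), and CYP82C2, outside that list, fell too (log2 -5.06 ± 0.07). Adding phl2, or the mutation labelled phl3, left 5 of 7 flavonoid genes higher (adjusted p = 2.35e-14) and 5 of 7 higher (adjusted p = 2.11e-12), with CHI at 3.72 ± 0.26, 3.24 with the class term, and at 3.75 ± 0.26, 3.04 with the class term. Adding phl2 to phr1phl1 called no list, and PHL2 itself was among its 33 genes (-2.91 ± 0.16). Between the libraries labelled quadruple and the triple mutant 2 of 27 photosynthesis genes were higher, or 4 higher adjusted over the list alone (adjusted p = 4.7e-08, and adjusted p = 0.277 with an estimated correlation), and QQS fell (log2 -2.15 ± 0.41).

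The steps called 781 higher and 922 lower genes for phl1, 845 higher and 609 lower for phl2, 2039 higher and 801 lower for the mutation labelled phl3 and 1571 higher and 1025 lower for phl4, each on phr1. The share of calls that were higher was 45.9% (38% after rescaling) for the first and 71.8% (64.7% after rescaling) for the third. The last 3 were 251 higher and 223 lower, 315 higher and 116 lower and 974 higher and 671 lower with the class term. The step to phr1phl2 called 2407 without phr1phl2 -Pi replicate 1, 913 without phr1phl2 -Pi replicate 2 and 888 without phr1phl2 -Pi replicate 3, and the share of its calls that were higher was 58.1% (43.1% after rescaling). The steps to the triple and the quadruple mutant called 13 higher and 20 lower and 103 higher and 32 lower genes, and in total 50 without phr1phl1phl2 -Pi replicate 1 and 87 without phr1phl1phl2phl3 -Pi replicate 2. Those 2 totals were 15 and 28 with only the groups compared in the fit, and 63 and 206 with a pseudocount of 0.1.

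A test of non-additivity asked whether 2 mutations together changed a gene by more or less than the sum of their log2 effects. For phr1 with phl1 7 of 17 phosphate transport genes were lower than the sum of both effects (adjusted p = 4.03e-09). 1 of 14 sulfate genes was higher and 6 lower (adjusted p = 3.14e-07). 6 of 14 immune response genes were lower (adjusted p = 3.32e-14), with CYP71A12 at -4.96 ± 0.15. Of the signalling genes, IPS1 was at -3.84 ± 0.44. For phr1 with phl4, 6 of 19 phosphatase and ribonuclease genes were lower, or 7 lower adjusted over the list alone (adjusted p = 6.34e-16). 3 of 15 lipid remodelling genes were lower (adjusted p = 2.25e-08). 22 of 27 photosynthesis genes were higher, or 24 higher adjusted over the list alone (adjusted p = 2.87e-30). Outside the lists, the sucrose exporter SWEET11 was at 4.12 ± 0.25 and CYP82C2 at -4.95 ± 0.09. Flavonoid genes stood above the sum in both other pairs. For phl2 4 of 7 flavonoid genes were higher, or 5 higher adjusted over the list alone (adjusted p = 8.58e-12), and for the libraries labelled phl3 5 of 7 higher (adjusted p = 3.3e-36), with FLS1 at 1.65 ± 0.23 and 2.49 ± 0.23. Non-additive genes numbered 595 higher and 674 lower for phl1, 54 higher and 104 lower for phl2, 135 higher and 53 lower for phl3 and 490 higher and 219 lower for phl4, and for phl2 the share of calls that were higher was 34.2% (23% after rescaling). With only the groups compared in the fit the totals were 366 for phl2 and 324 for phl3. Under -Pi PHL3 read 15.2 ± 0.946 in the libraries labelled phl3 but 3.48 ± 0.513 in phr1phl3. The values for that pair are thus by label, and do not test whether losses of PHR1 and PHL3 add up.

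Under +Pi the mutants were compared with Col to ask what the family does when phosphate is supplied. Flavonoid genes were lower in 10 of the 11 mutants. The count was 5 of 7 lower in phr1 (adjusted p = 7.74e-16), 5 of 7 lower in phl1 (adjusted p = 3.14e-18), 6 of 7 lower in phl2 (adjusted p = 2.22e-15), 6 of 7 lower in the libraries labelled phl3 (adjusted p = 1.47e-15) and 5 of 7 lower in phl4 (adjusted p = 6.81e-25). The doubles and the triple had 6 of 7 lower in phr1phl1 (adjusted p = 4.84e-18), 5 of 7 lower in phr1phl2 (adjusted p = 2.24e-11), 6 of 7 lower in phr1phl3 (adjusted p = 2.23e-19), 6 of 7 lower in phr1phl4 (adjusted p = 1.8e-23) and 6 of 7 lower in phr1phl1phl2 (adjusted p = 2.43e-23). In the quadruple mutant 0 of 7 were called (median log2 -0.44, adjusted p = 0.0654). FLS1 read 4.63 ± 1.13 against 151 ± 35.5 in phr1phl1, and CHS fell in phr1phl4 (log2 -4.52 ± 0.10, -4.50 with the class term). 2 of 22 iron uptake genes were higher and 6 lower in phl4 (adjusted p = 3.21e-08), with IRT1 at 94.3 ± 2.4 against 341 ± 164 (adjusted p = 0.265 in a fit of phl4 and Col alone), and 2 of 22 higher and 8 lower in phr1phl4 (adjusted p = 2.27e-07), with CYP82C4 at -3.49 ± 0.11, -3.52 with the class term. In phr1phl2 7 of 22 were lower (adjusted p = 4.49e-05) and in phr1phl3 1 of 22 higher and 7 lower (adjusted p = 3.79e-08). The IPS1 relative AT4 fell to 2.6 ± 0.728 in phr1phl1, 3.38 ± 2.85 in the triple and 1.42 ± 0.169 in the quadruple mutant from 493 ± 270 in Col. In the quadruple mutant SPX1 fell (log2 -3.35 ± 0.22, -2.35 with the class term) and PHO2 rose (log2 1.94 ± 0.28, 1.3 with the class term). 7 of 14 sulfate genes were higher in phr1phl2 (adjusted p = 1.63e-14). The nitrate transporter NRT2.1 also rose there (log2 3.08 ± 0.12, 2.99 with the class term). The 11 comparisons share the 3 Col +Pi libraries, so a difference in those alone would appear in all of them.

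Counts under +Pi were sensitive to the classes and to the fit. They were 159 higher and 361 lower in phr1, 116 higher and 736 lower in phl1, 259 higher and 2138 lower in phl2, 352 higher and 1909 lower in the libraries labelled phl3, 141 higher and 209 lower in phl4, 287 higher and 1521 lower in phr1phl1, 141 higher and 1121 lower in phr1phl2, 237 higher and 295 lower in phr1phl3, 639 higher and 549 lower in phr1phl4, 121 higher and 1105 lower in the triple and 105 higher and 1504 lower in the quadruple mutant. Totals in that order were, from the fit with the class term, 210, 287, 417, 387, 403, 433, 301, 345, 1451, 448 and 187. Fits of each mutant and Col alone gave 38, 36, 1764, 1705, 15, 511, 200, 209, 972, 47 and 1055, and a pseudocount of 0.1 gave 757, 1309, 3521, 3465, 642, 2779, 2006, 866, 1871, 1877 and 2442. The share of calls that were higher was 30.6% (36.3% after rescaling) for phr1, 13.6% (19.5% after rescaling) for phl1, 10.8% (20% after rescaling) for phl2, 15.6% (29.1% after rescaling) for the libraries labelled phl3, 40.3% (28.3% after rescaling) for phl4, 15.9% (24.3% after rescaling) for phr1phl1, 11.2% (15.1% after rescaling) for phr1phl2, 44.5% (40.9% after rescaling) for phr1phl3, 53.8% (43.1% after rescaling) for phr1phl4, 9.9% (12.4% after rescaling) for the triple and 6.5% (9.8% after rescaling) for the quadruple mutant. Totals over 1.5 times apart when 1 library was left out were, for phr1, 89 without Col +Pi replicate 1, 1944 without Col +Pi replicate 2, 213 without phr1 +Pi replicate 1, 320 without phr1 +Pi replicate 2 and 336 without phr1 +Pi replicate 3, for phl1 196 without Col +Pi replicate 1, 1967 without Col +Pi replicate 2 and 538 without phl1 +Pi replicate 3, for phl2 1575 without Col +Pi replicate 1, for phl4 996 without phl4 +Pi replicate 3, for phr1phl1 2897 without phr1phl1 +Pi replicate 1, for phr1phl2 2069 without Col +Pi replicate 2 and 669 without phr1phl2 +Pi replicate 1, for phr1phl3 277 without Col +Pi replicate 1 and 1599 without Col +Pi replicate 2 and for the triple mutant 778 without phr1phl1phl2 +Pi replicate 1, 3100 without phr1phl1phl2 +Pi replicate 2 and 747 without phr1phl1phl2 +Pi replicate 3.

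How much of the response each mutant kept was measured over the 1323 genes induced in Col, as the median share of the Col log2 change. Mutants carrying phr1 and 1 more mutation kept less than phr1 in these values. The shares were 78.2% ± 1.4 (SD) for phr1, 83.4% ± 7.4 for phl1, 86.9% ± 1.7 for phl2, 92.0% ± 1.2 for the libraries labelled phl3, 65.9% ± 4.0 for phl4, 64.9% ± 1.6 for phr1phl1, 63.0% ± 6.3 for phr1phl2, 51.2% ± 0.8 for phr1phl3, 39.3% ± 5.3 for phr1phl4, 62.9% ± 2.5 for the triple and 52.7% ± 11 for the quadruple mutant, against 100.1% ± 0.5 in Col. A simulated unchanged genotype kept 95.6%, because the genes were chosen on the Col libraries. The exact two-sided permutation p against Col was 0.1 for each mutant, the smallest that 20 assignments of 3 against 3 allow. It decides nothing, since the unchanged genotype, at 94.7% to 96.4% in 20 draws, lies below every Col library too. Without Col +Pi replicate 1, phl2 kept 100.8% and the libraries labelled phl3 103.6%, against 100.2% in Col, so neither is shown to keep less than Col. Without Col +Pi replicate 2, phr1 kept 60.8% ± 2.9, phr1phl1 60.4% ± 4.6, the triple mutant 62.3% ± 1.9 and phr1phl3 25%. There phr1phl1 lay below phr1 by less than its SD, and the triple mutant lay above phr1. With the class term the order changed, with phr1 at 86.6% ± 0.5, phl2 at 95.4% ± 1.9, the libraries labelled phl3 at 97.7% ± 0.3, phl4 at 76.9% ± 2.2, phr1phl1 at 53.9% ± 1.4, phr1phl3 at 71.3% ± 0.6, phr1phl4 at 49.1% ± 2.0, the triple at 55.2% ± 4.3 and the quadruple mutant at 48.9% ± 3.4.

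**Figure D4:**
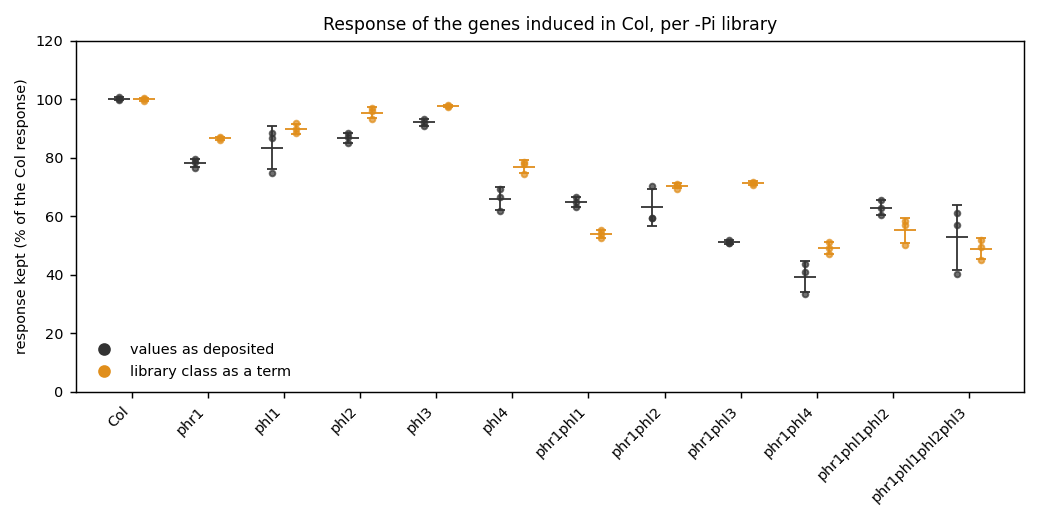
Share of the Col response kept over the genes induced in Col, in percent, 1 point per -Pi library with the mean and SD per genotype. Col lies at 100.1%, phr1 at 78.2% and phr1phl4 at 39.3%.

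Responses were also compared gene by gene, as the difference between a mutant's response and that of Col. Genes induced in Col with a smaller response numbered 173 in phr1, 87 in phl1, 243 in phl2, 190 in the libraries labelled phl3, 331 in phl4, 392 in phr1phl1, 409 in phr1phl2, 558 in phr1phl3, 580 in phr1phl4, 391 in the triple and 483 in the quadruple mutant. Numbers with the class term were, in that order, 152, 26, 61, 40, 219, 421, 297, 320, 496, 420 and 465. In phr1phl1 the response of lipid remodelling genes was lower for 9 of 15 (adjusted p = 3.32e-18) and that of sulfate genes lower for 7 of 14 (adjusted p = 1.9e-09), while that of photosynthesis genes was higher for 24 of 27 (adjusted p = 2.69e-16). The response of the signalling gene SPX3 differed by -5.62 ± 0.29. In phr1 the response of immune genes was higher for 9 of 14 (adjusted p = 1.35e-16), with CYP71A12 at 5.51 ± 0.15. In phl4 that of root hair genes was higher for 5 of 16 (adjusted p = 1.5e-07) and that of iron uptake genes higher for 9 of 22 and lower for 1 of 22 (adjusted p = 2.43e-05). All genes with a different response numbered 1203 in phr1, 1857 in phl1, 7452 in phl2, 6926 in the libraries labelled phl3, 2115 in phl4, 3776 in phr1phl1, 6395 in phr1phl2, 7349 in phr1phl3, 3159 in phr1phl4, 3480 in the triple and 6415 in the quadruple mutant. In the fit with the class term these were 1165, 265, 1271, 748, 1126, 2582, 2516, 2452, 2389, 2999 and 3519.

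In these tests of the response, leaving out 1 library moved totals by over 1.5 times as follows. For phr1 they were 743 without Col +Pi replicate 1 and 2358 without Col +Pi replicate 2, for phl1 166 without Col +Pi replicate 1, 3689 without Col +Pi replicate 2, 1213 without phl1 +Pi replicate 1, 1178 without phl1 +Pi replicate 3, 1058 without Col -Pi replicate 2, 812 without Col -Pi replicate 3, 3806 without phl1 -Pi replicate 1, 2857 without phl1 -Pi replicate 2 and 142 without phl1 -Pi replicate 3, for phl4 1118 without Col +Pi replicate 1, 3460 without Col +Pi replicate 2, 1153 without phl4 +Pi replicate 2, 4794 without phl4 +Pi replicate 3, 3480 without phl4 -Pi replicate 2 and 1348 without phl4 -Pi replicate 3 and for the triple mutant 5824 without phr1phl1phl2 +Pi replicate 2. With only the groups compared in the fit totals were 24 for phl1, 735 for phl4 and 1899 for the triple mutant. The share of calls that were higher was 76% (70% after rescaling) for phr1, 77.8% (69.8% after rescaling) for phl1, 67.2% (62.6% after rescaling) for phl2, 71.3% (61.5% after rescaling) for the libraries labelled phl3, 57.6% (72.5% after rescaling) for phl4, 76.1% (59.5% after rescaling) for phr1phl1, 76.4% (65.2% after rescaling) for phr1phl2, 64.8% (59.6% after rescaling) for phr1phl3, 63.8% (65.5% after rescaling) for phr1phl4, 78.5% (64.2% after rescaling) for the triple and 73.9% (63.1% after rescaling) for the quadruple mutant. Rescaling each library by its median ratio moved the median log2 of all genes by over 0.1 in the response differences of the libraries labelled phl3 (-0.116), phr1phl1 (-0.159), phr1phl2 (-0.138), the triple (-0.151) and the quadruple mutant (-0.134), and under -Pi in phr1phl2 (-0.107) and the triple mutant (-0.104) against Col.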

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

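The tests of library class and those of PHL3 were chosen after the result was seen, and the tests of base content and length and of shoot markers before. In the libraries of phl2 and in those labelled phl3, 3210 and 2934 genes were called against Col under -Pi, and all 6 libraries were class 2 while those of Col were class 1. GC content or gene length as the whole cause is argued against, since with that trend removed 70.5% of 3159 calls for phl2 and 66.2% of 2892 for phl3 were still called, with a median absolute log2 fold change of 1.33 before and 1.19 after for phl2 (median SE 0.34 and 0.29). A difference between library batches, seen as the class, is a candidate explanation for much of it, since the class 2 minus class 1 difference inside 5 other -Pi groups followed phl2 minus Col across 21206 genes with r = 0.86 (phl3 0.87, single groups 0.64 to 0.91). With the class term 222 and 118 genes were called, and loss of PHL2, growth on agar or agarose and a library batch stay open, because the labels name no batch or plate per library.

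Photosynthesis genes, which fell in Col under -Pi with a median response of -3.33, had a median response of 0.53 in phr1phl1 and 0.93 in phr1phl4, differences that passed camera (adjusted p = 2.69e-16 and 8.32e-31, and 0.0214 and 0.00124 with an estimated correlation). With the class term the median response was 0.19 in phr1phl1 and 0.68 in phr1phl4, against -3.16 in Col. The medians of the other mutants also lay above that of Col. They were -0.03 in the quadruple mutant, -0.68 in phr1phl3, -1.22 in the triple mutant, -1.24 in phr1phl2 and -1.38 in phl4. In phl2, phr1, the libraries labelled phl3 and phl1 they were -1.54, -1.72, -2.3 and -2.53. Camera did not call the libraries labelled phl3 (adjusted p = 0.361). With an estimated correlation it called only phl4 of these (adjusted p = 0.0379). All responses were compared with the same Col libraries. In phr1phl1 under -Pi 21 of 27 genes were higher than in Col with all 6 libraries of class 1. This argues against the library class as the cause of those levels. The response also uses +Pi libraries, which were all class 3 in phr1phl1 and class 1 or 2 in Col. A batch that the classes do not mark stays open. Green tissue carried over with the root cannot be told apart from a change in the root itself, since of 13 shoot markers 7 were tested and 5 reached 5 RPKM, and in 4 mutants 8 of 28 tests were higher and 3 lower. In phr1phl4 4 of 7 markers were higher, namely KCS6 (log2 2.92 ± 0.13, 14.5 ± 1.47 against 1.06 ± 0.343 RPKM), TGG1 (2.87 ± 0.29), PDF1 (1.39 ± 0.15, from 17.6 ± 2.12) and FDH (1.02 ± 0.11, from 10.8 ± 0.919), while TGG1 rose in phr1phl1 (1.44 ± 0.29), the triple (1.1 ± 0.29, at 2.64 ± 3.92 RPKM) and the quadruple mutant (1.65 ± 0.29), KCS6 rose in the quadruple mutant (1.37 ± 0.13), and CER1 fell in phr1phl1, the triple and the quadruple mutant (-1.37 ± 0.12, -1.39 ± 0.12 and -1.05 ± 0.12). Green tissue, light on the root and a response of root plastids stay open.

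PHL3 was not lower in the libraries labelled phl3 and quadruple. The library class is argued against as the cause, since with the class term PHL3 still had a log2 fold change of 0.64 in the libraries labelled phl3 under -Pi. Libraries swapped with another group are argued against too, since 0 of the 54 libraries with no phl3 in their label were at or below 3.87 RPKM, the highest value in phr1phl3. That margin is narrow, as the lowest of the 54 read 3.99. A wrong label without a partner, and an allele that leaves the transcript in place, stay open, and no biological explanation was tested.

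Flavonoid genes also responded differently from Col, where their median response was -2.75, with 0.98 in phl2 (camera adjusted p = 9.74e-11), 0.76 in phr1phl3 (adjusted p = 3.45e-10) and 0.91 in phr1phl4 (adjusted p = 8.11e-15). These responses were 0.67, 0.55 and 0.46 with the class term. The difference is not particular to these 3, as the median response was also 0.37 in the libraries labelled phl3 (adjusted p = 1.65e-09), 0.29 in phr1phl2 (3.64e-10), 0 in phr1phl1 (2.71e-10), -0.02 in the triple mutant (3.27e-11) and -0.3 in phl4 (1.71e-16). It was -2.09 in phr1 (0.000163) and -1.85 in phl1 (0.00631, and 0.215 with an estimated correlation). In the quadruple mutant it was -1.82 (0.0442, and 0.175 with an estimated correlation). As given above, flavonoid genes were already lower than in Col under +Pi in every mutant but the quadruple. The differences in response thus lie at least in part in the +Pi levels. They all use the same 3 Col +Pi libraries, of which replicate 1 was class 2.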

How the results depend on the processing

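Each alternative changed 1 choice, except that with genes chosen on 2 Col replicates the Col response also came from another library. With no filter, with rescaling and with the replicate number as a block all 45 counts stayed within 1.5 times. With the block the Col response had 1323 higher and 1731 lower genes. Libraries of the same number were not paired in most comparisons, since in 2 of 29 every correlation of their deviations was above 0.1. These were phr1phl1 (0.54, 0.29 and 0.41) and phr1phl3 (0.45, 0.21 and 0.21) against Col under +Pi, where a shared batch stays open. Within 1.5 times, or within 1 SD for the percent kept, were 20 of 45 counts and 2 of 11 shares kept with the class term, 13 of 18 counts and 1 of 2 shares kept with class 1 libraries only, 31 of 45 counts and 6 of 11 shares kept with a pseudocount of 0.1, 29 of 45 counts with only the groups compared in the fit, and 316 of 360 counts and 102 of 132 shares kept with 1 library left out. Of 155 gene values checked, all kept their call with rescaling, the class term, no filter and the block. So did all 103 that class 1 libraries could test. Of the 155, 6 lost it in the fit of compared groups, 3 with a pseudocount of 0.1, and 2 refits with 1 library left out lost a call. PHL4 stood apart, as its calls in phl4 against Col and in phr1phl4 against phr1, both under -Pi, ended with the class term. The class term and class 1 fits were chosen after seeing the data. A group left with 2 libraries is assumed to vary like the others. Fewer libraries or class 1 alone leave less to test, and otherwise the cause was not tested. Depth limits low genes, as 1 RPKM in 1 kilobase is 11 reads at the lowest depth.

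Some totals moved with a pseudocount of 0.1. Against Col under -Pi they were 1079 for phr1, 96 for phl1, 2776 for phl4. Against Col under +Pi they were 1309 for phl1, 3465 for phl3, 642 for phl4, 2779 for phr1phl1, 2006 for phr1phl2, 866 for phr1phl3, 1871 for phr1phl4, 1877 for the triple, 2442 for the quadruple. For steps they were 63 for the triple on phr1phl1, 206 for the quadruple on the triple. Percent kept was 80.5 for phr1, 93.3 for phl3, 70.1 for phr1phl1, 55.4 for phr1phl3, 69.2 for the triple.

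The next values moved with only the groups compared in the fit. Against Col under -Pi they were 4 for phl1. Against Col under +Pi they were 38 for phr1, 36 for phl1, 15 for phl4, 511 for phr1phl1, 200 for phr1phl2, 209 for phr1phl3, 47 for the triple, 1055 for the quadruple. For steps they were 15 for the triple on phr1phl1, 28 for the quadruple on the triple. For differences in response they were 24 for phl1, 735 for phl4, 1899 for the triple. For non-additivity of phr1 they were 366 with phl2, 324 with phl3.

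The next values moved with the class term. Against Col under -Pi they were 222 for phl2, 118 for phl3, 729 for phl4, 1354 for phr1phl2, 1403 for phr1phl3, 2669 for phr1phl4. Against Col under +Pi they were 210 for phr1, 287 for phl1, 417 for phl2, 387 for phl3, 433 for phr1phl1, 301 for phr1phl2, 345 for phr1phl3, 448 for the triple, 187 for the quadruple. For steps they were 474 for phr1phl2 on phr1, 431 for phr1phl3 on phr1, 1645 for phr1phl4 on phr1. For differences in response they were 265 for phl1, 1271 for phl2, 748 for phl3, 1126 for phl4, 2516 for phr1phl2, 2452 for phr1phl3, 3519 for the quadruple. Percent kept was 86.6 for phr1, 95.4 for phl2, 97.7 for phl3, 76.9 for phl4, 53.9 for phr1phl1, 70.4 for phr1phl2, 71.3 for phr1phl3, 49.1 for phr1phl4, 55.2 for the triple.

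The next moved with class 1 libraries only. Against Col under +Pi they were 139 for phr1, 355 for phl1, 718 for phl4, 334 for phr1phl3. For differences in response they were 210 for phl1. Percent kept was 87.7 for phr1.

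The next moved with rescaling. Percent kept was 75.8 for phr1, 85.2 for phl2, 86.9 for phl3, 72.1 for phl4, 54.3 for phr1phl1, 55.6 for phr1phl2, 47.3 for phr1phl3, 52 for the triple.

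The next moved with genes chosen on 2 Col replicates. Percent kept was 84.5 for phr1, 90.3 for phl2, 95.3 for phl3, 67.3 for phr1phl1, 66.3 for the triple.

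Totals had these lowest and highest values with 1 library left out. Against Col under -Pi they were 39 to 80 for phl1, 1170 to 3085 for phl4. Against Col under +Pi they were 89 to 1944 for phr1, 196 to 1967 for phl1, 1575 to 3362 for phl2, 285 to 996 for phl4, 1302 to 2897 for phr1phl1, 669 to 2069 for phr1phl2, 277 to 1599 for phr1phl3, 747 to 3100 for the triple. For steps they were 888 to 2407 for phr1phl2 on phr1, 27 to 50 for the triple on phr1phl1, 87 to 195 for the quadruple on the triple. For differences in response they were 743 to 2358 for phr1, 142 to 3806 for phl1, 1118 to 4794 for phl4, 2651 to 5824 for the triple. Percent kept was 60.8 to 87.8 for phr1, 67 to 91.8 for phl1, 68.9 to 101 for phl2, 77.5 to 104 for phl3, 46.2 to 76.6 for phl4, 60.4 to 65.6 for phr1phl1, 47.2 to 75.7 for phr1phl2, 25 to 68 for phr1phl3, 26.9 to 47.6 for phr1phl4, 60.2 to 64.2 for the triple. Without Col +Pi replicate 1 the libraries labelled phl3 kept 103.6%, above Col at 100.2%, and phl2 kept 100.8% (exact p 0.4), so that the direction against Col turned for phl3 and was lost for phl2.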

Other observations

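Other gene groups moved in the mutants in ways not described above. 5 of 12 endodermal barrier genes were lower in phr1phl4 under +Pi (adjusted p = 5.03e-12) and 4 of 12 lower in the triple mutant (adjusted p = 0.000277), and under -Pi 3 of 12 lower in phr1phl3 (adjusted p = 4.8e-07). Jasmonate genes, which rose in Col, had a smaller response in phl4, where 7 of 16 were lower than in Col (adjusted p = 4.4e-05), and in phr1phl4, with 10 of 16 lower (adjusted p = 6.49e-11). Under -Pi 1 of 16 jasmonate genes was higher and 6 lower when phl4 was added to phr1 (adjusted p = 7.83e-07). The response of phosphatase and ribonuclease genes in phl4 was above that of Col, with 4 of 19 higher (adjusted p = 7.95e-09). Under +Pi 3 of 14 sulfate genes were higher in phr1phl3 (adjusted p = 9.41e-10).

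Some genes of unstated function differed between lines. AT3G01345 read 65.4 ± 5.25 against 0.282 ± 0.0701 RPKM in phr1 and Col under -Pi and 68.3 ± 5.5 against 0.482 ± 0.14 under +Pi, with 118 ± 10.9 in phr1phl2, 115 ± 2.72 in phr1phl3 and 122 ± 8.1 in the quadruple mutant under -Pi, but 0.431 ± 0.111 in phr1phl1 and 1.29 ± 0.362 in the triple mutant. AT4G03760 read 15.7 ± 0.394 in phr1, 7.09 ± 2.41 in phl1 and 20.8 ± 4.94 in the triple mutant under -Pi, against 0.0123 ± 0.0107 in Col and 0.00783 ± 0.0136 in phr1phl4, but its call in phl1 ended in a fit of phl1 and Col alone (adjusted p = 0.0742). The non-coding RNA gene AT1G67105 read 292 ± 60.6 in phr1phl1 and 6.82 ± 2.09 in the triple mutant, against 0.0871 ± 0.0765 in Col. MRD1 read 41.9 ± 0.772 in Col, 50.2 ± 3.39 in phr1phl3 and 53.4 ± 7.2 in the quadruple mutant, against 1.58 ± 0.0704 in phr1, 1.03 ± 0.183 in phl2 and 0.697 ± 0.122 in the triple mutant, and its span overlaps another gene, so its values are uncertain.

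The tests of motifs were written before their result was seen, and the splits of libraries afterwards. If genes induced in Col depend on direct binding of the family, those with a smaller response in the mutants may carry the P1BS motif that PHR1 binds more often within 1000 bp upstream. Of the 160 such genes in phr1, 40% had the motif against 26.8% of the other 1091 induced genes (odds ratio 1.82, interval 1.27 to 2.6, Fisher exact adjusted p = 0.00144). In phr1phl1 it was 32.5% of 366 against 26.8% of 885 (odds ratio 1.32, interval 1 to 1.73, adjusted p = 0.0457), and 20.7% of all 20152 tested protein-coding genes had it. The size of induction was not matched between the sets, so a link of the motif with strong induction alone stays open.

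Splits of the libraries compared, other than the real one, were refitted. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In 28 of 30 such results 1 split, the real one, reached the real count. Counts for the real split against the highest other were 1323 against 7 for genes induced in Col and 1738 against 7 for genes repressed. Against Col under -Pi they were 658 against 1 for phr1, 53 against 1 for phl1, 3210 against 0 for phl2, 2934 against 0 for the libraries labelled phl3, 1836 against 4 for phl4, 2440 against 1 for phr1phl1, 3049 against 2 for phr1phl2, 4311 against 1 for phr1phl3, 4013 against 1 for phr1phl4, 2633 against 2 for the triple and 3624 against 0 for the quadruple mutant. Under +Pi, in the same order, they were 520 against 75, 852 against 344, 2397 against 3, 2261 against 371, 350 against 1597, 1808 against 857, 1262 against 754, 532 against 3, 1188 against 193, 1226 against 2599 and 1609 against 1. For the steps from phr1 to its doubles with phl1, phl2, phl3 and phl4 they were 1703 against 0, 1454 against 3, 2840 against 1 and 2596 against 0, and for the steps to the triple and the quadruple mutant 33 against 5 and 135 against 21. For phl4 under +Pi 4 of 10 splits, and for the triple mutant 3 of 10, gave as many genes. Their highest others put the class 2 libraries together on 1 side and so follow the library classes, and with the class term the real counts were 403 and 448.

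For tests of 4 groups 100 splits were drawn, after 30 had been drawn and seen, in which libraries were exchanged within a medium for the response and within genotypes with or without phr1 for non-additivity. The number of splits with as many genes as the real one, itself included, was 1 (real count 1203, highest other 910) for the response of phr1, 1 (real count 7452, highest other 5778) for phl2, 1 (real count 6926, highest other 5572) for the libraries labelled phl3, 4 (real count 3776, highest other 4679) for phr1phl1, 1 (real count 6395, highest other 5756) for phr1phl2, 1 (real count 7349, highest other 6425) for phr1phl3 and 1 (real count 6415, highest other 5506) for the quadruple mutant, a share under 0.05 for these 7. For phr1 no other split drawn reached the real count, which argues against chance within these 100 splits. The libraries of phr1 and Col are class 1 except Col +Pi replicate 1, which is class 2. Without that library 743 genes were called for phr1. For the other 6 the real grouping also follows the library classes in whole or in part, and for phr1phl1 another split called more genes, so these splits do not set the mutation apart from the class. In that order the 7 counts with the class term were 1165, 1271, 748, 2582, 2516, 2452 and 3519. It was 6 (real count 1857, highest other 2896) for phl1, 8 (real count 2115, highest other 6547) for phl4, 6 (real count 3159, highest other 6669) for phr1phl4 and 6 (real count 3480, highest other 4868) for the triple mutant, and chance cannot be excluded for them. The same holds for the non-additivity of phr1 with phl1, 10 (real count 1269, highest other 2396), with phl2, 16 (real count 158, highest other 7460), with phl3, 13 (real count 188, highest other 8190), and with phl4, 13 (real count 709, highest other 7541). Many of these other splits kept some groups whole, exchanged whole groups or put libraries of 1 class together, so they hold real differences and the structure of the samples. The real counts with the class term were 265, 1126, 2389 and 2999 for the responses and 1530, 221, 253 and 862 for non-additivity.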
